A study of Mus musculus with 16 samples.

How the data were processed

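RNA of femur and white adipose tissue from 8 mice was measured on 16 Illumina bead arrays, 4 for each tissue and genotype. Per the labels' protocols, total RNA was extracted with Trizol and column cleanup and amplified to biotin-labelled cRNA. The values used were the deposited intensity of each of 25697 probes on a linear scale, made by the authors with GenomeStudio 2011.1 per the submitters' processing notes. The methods of background correction and normalization are not given in the sources used here. The intensities included negative values (25.3% to 25.4% of probes per array), as after background subtraction. Sorted intensities of the 16 arrays differed by at most 0.797 and at the median by 0.0676, as after quantile normalization over both tissues together, so a difference in total RNA between arrays is not visible in them. A table of signals before normalization was not used, since its 16 signal columns carry names that match no sample label. The design fixed before the data were examined had planned background correction and quantile normalization of that table (neqc) and a filter on detection p-values; the authors' normalized intensities, planned as an alternative, took its place.

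Intensities below 16 were set to 16 and taken to log2, so fold changes of dim probes are understated. A probe was kept in a tissue if it exceeded 16 on at least 4 of the 8 arrays. This filter was chosen after the files were seen, and the first setting tried was kept. Probe names came from the platform annotation: 23978 probes had 1 gene, 0 had several and 1719 were unnamed, and 23971 symbols were updated through the RefSeq gene table of assembly GRCm38.p6. A gene with several kept probes was given by its brightest probe in the tissue. Of 2613 such genes in each tissue, all probes had 1 sign for 56.8% in femur and 63.0% in white adipose tissue.

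Genotypes were compared in each tissue with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The genotype effect was compared between tissues in 1 fit of all 16 arrays with the animal as a random block (duplicateCorrelation, consensus correlation -0.0884), since the labels give the femur and white adipose samples of an animal the same replicate number and animal identifier. The deviations of an animal's femur and white adipose arrays from their group means correlated between -0.29 and 0.04. Single genes of the endothelin pathway were also tested with an exact permutation test over 70 relabelings, whose smallest p is 0.0286. Of 37 gene lists fixed from textbook markers, the 35 in each tissue with at least 5 measured genes were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and neither called any list in femur or white adipose tissue at an adjusted p of 0.05. For the difference between tissues, camera was run on the femur minus white adipose difference within each animal, a step added after the data were seen, as were its alternatives.

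The comparisons, the gene lists, the rule for naming genes, except its ranking by the brightest probe, and most alternatives were set before the data were examined. Set after were the floor of 32, the offset scale, the stricter dim-probe filter, the renormalizations, the adjusted p of 0.20 and omissions from the fit of all 16 arrays. The rule took the called genes, the 10 genes of smallest p where fewer were called, the 5 called genes of smallest p in each direction for the difference between tissues, the endothelin pathway, up to 4 genes of smallest p from each called list and up to 2 of highest signal from other lists. The 10 of smallest p were first ranked by any probe and then, after the first table was seen, by the gene's brightest probe. The genotype values of Lep and Adipoq were named after they were seen. Per-array list means and the counts of splits per list were added later too.

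Calling was tested on simulated data made from the real means and spreads, with 100 probes changed at each size. Each probe was drawn independently, without variation shared among probes of an array and without the floor, and only brighter probes were changed. Recovery near the floor or under shared variation was therefore not tested. In femur, over 14281 probes, 49% of 1.5-fold and 100% of 3-fold changes were recovered with 10 false calls. In white adipose tissue, over 14342 probes, the shares were 41% and 96% with 5 false calls. Alternatives covered the dim-probe filter, floor, scale, renormalization, variance model, array weights, 1 fit of all 16 arrays for the effect within each tissue, blocks, threshold, probes per gene and leaving out each replicate, or the pair of animals with 1 identifier. Other splits of the 8 animals into groups of 4 were counted, 35 in all. The number of arrays limits the precision, and the level of Ednra is not analysed here.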

Results

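Gene expression was measured in femur and white adipose tissue of 8 male mice of the inbred strain C3HeB/FeJ at 17 weeks of age, on 16 Illumina bead arrays. The 8 mice were 4 wild-type animals and 4 animals of line AEA001, which was made with the mutagen ENU and is described by its submitters as an osteoporosis model with a mutation in Ednra, the gene of endothelin receptor type A. Each of the 4 combinations of tissue and genotype held 4 arrays. The labels gave 7 animal identifiers for the 8 mice, since wild type replicate 3 and AEA001 mutant replicate 4 shared 1. Values were the authors' normalized probe intensities, with array medians between 25.2 and 25.3 and between 14204 and 14227 of the 25697 probes above an intensity of 16. An array has no read depth, and the number of arrays limits the precision. Fold changes below are AEA001 mutant minus wild type on the log2 scale, given with limma's moderated SE from 4 arrays per genotype. The SE of a difference between tissues is from the fit of all 16 arrays. Adjusted p-values are from limma or its set test camera, all two-sided.

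The arrays carried the marker transcripts of their tissue. Adipoq, which encodes the adipocyte hormone adiponectin, had an intensity of 17156 ± 1084 (SD, n = 4) in wild-type white adipose tissue and 2020 ± 325 (SD, n = 4) in wild-type femur. Bglap, which encodes osteocalcin of bone matrix, reached 13302 ± 2139 (SD, n = 4) in wild-type femur and -8.99 ± 2.58 (SD, n = 4) in wild-type white adipose tissue. S100a8, an abundant granulocyte transcript, was at 25545 ± 444 (SD, n = 4) in wild-type femur. An exception was the white adipose array of AEA001 mutant replicate 2, where Bglap was at 242 and S100a8 at 9828. Of 71 probes with a femur mean above 1000 and no more than 16 on the other 7 white adipose arrays, 61 exceeded 16 on that array, at a median of 1.58% of their femur signal. The same count on each of the other white adipose arrays gave 0 of 10 probes. Those 10 had to lie at or below 16 on AEA001 mutant replicate 2 too, so the 0 says little about femur transcripts on the other arrays.

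**Figure D1:**
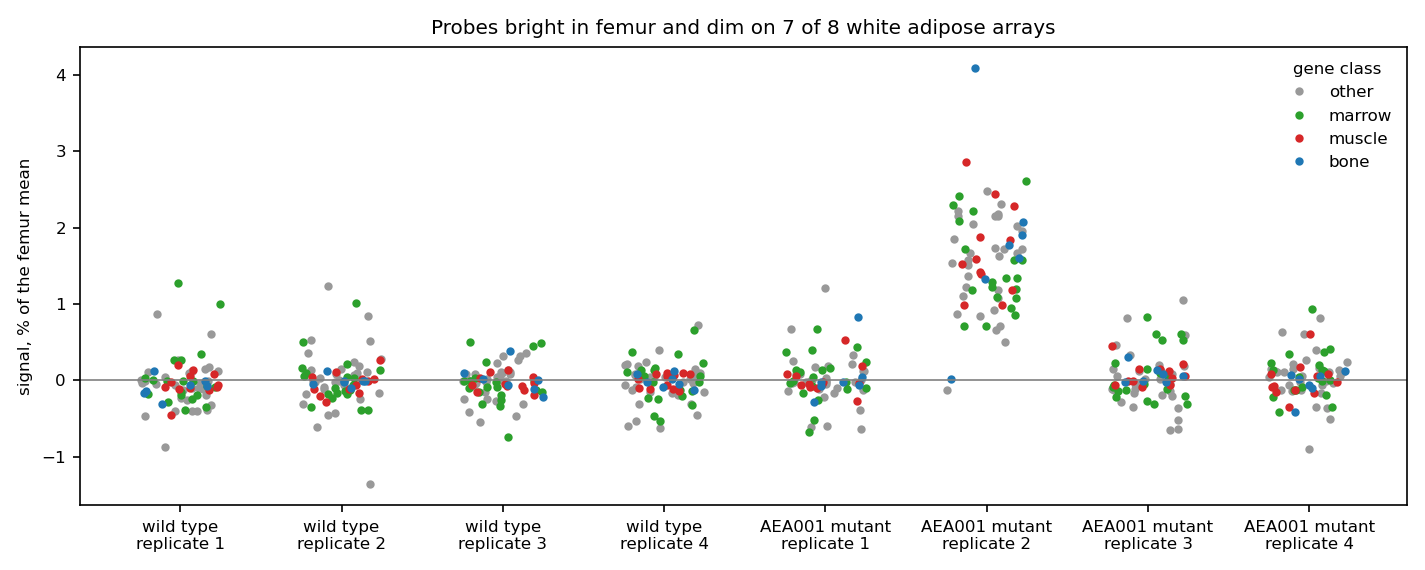
Signal of each of 71 probes that were bright in femur (mean above 1000) and at or below 16 on 7 of the 8 white adipose arrays, as a percent of its femur mean, on every white adipose array. Each point is 1 probe coloured by gene class, and on AEA001 mutant replicate 2 the median was 1.58%.

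The transcript of Ednra itself is not analysed here. Of the other members of the endothelin pathway, 6 were measured in femur and 5 in white adipose tissue, and 0 passed the limma threshold in either tissue. By the brightest probe of each gene, 2 were lower in femur and 1 in white adipose tissue at an unadjusted p under 0.05. Ece1, which encodes an enzyme that releases active endothelin, was -0.70 ± 0.24 in femur (limma adjusted p = 0.214, exact permutation p = 0.0571). Kel, whose product also cleaves endothelin precursors and is a red-cell antigen, was -0.37 ± 0.13 in femur (limma adjusted p = 0.222). Ednrb, which encodes the type B receptor, was 0.32 ± 0.19 in femur (limma adjusted p = 0.416) and 0.02 ± 0.08 in white adipose tissue (limma adjusted p = 0.912). A dimmer probe of Ednrb was 0.48 ± 0.13 in femur (limma adjusted p = 0.182). In white adipose tissue, dimmer probes of Ednrb and Ece1 were -0.71 ± 0.32 and 0.39 ± 0.17, each of the other sign than the brightest probe. The value of Ednrb by its brightest probe in white adipose tissue took the opposite sign without wild type replicate 1 (-0.016) or AEA001 mutant replicate 2 (-0.0057) and after cyclic loess normalization. Edn1, which encodes endothelin itself, was -0.31 ± 0.26 in femur and 0.30 ± 0.15 in white adipose tissue, where the limma adjusted p was 0.244. Mme, the peptidase neprilysin, was lower in white adipose tissue at -0.64 ± 0.14 (limma adjusted p = 0.112, exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give), and it was the only member past the threshold adjusted over the list alone in that tissue, against 0 in femur. It passed over all probes in 1 fit of all 16 arrays (limma adjusted p = 0.0453), which called 0 white adipose probes without wild type replicate 1 or 2 or AEA001 mutant replicate 4. Without the pair of arrays that share 1 animal identifier, Ece1 in femur was -1.04 (limma adjusted p = 0.0323).

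The femur comparison asked which transcripts differ between mutant and wild-type bone. By camera at its preset correlation, the lists of granulocyte, macrophage and mast cell genes were higher in the mutants and those of red-cell precursors and bone matrix lower, while 0 of their genes passed the limma threshold over all probes and 0 lists passed with an estimated correlation. The neutrophil and granulocyte list rose, with 25 of 26 measured genes higher and a median of 0.34 (camera adjusted p = 2.80e-09, adjusted p = 0.80 with an estimated correlation). The macrophage and dendritic cell list rose, with 18 of 20 genes higher and a median of 0.37 (camera adjusted p = 1.43e-07, adjusted p = 0.80 with an estimated correlation), as did the mast cell, basophil and eosinophil list, with 13 of 13 higher and a median of 0.41 (camera adjusted p = 0.000253, adjusted p = 0.80 with an estimated correlation). Over all probes, 0 genes of the 3 lists passed the limma threshold, and 12, 12 and 6 of them were higher at an unadjusted p under 0.05. Adjusted over the list alone, 8 granulocyte genes passed, and 0 of the other two lists.

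Among granulocyte genes, Padi4, which citrullinates histones in neutrophils, was 0.76 ± 0.15 higher (limma adjusted p = 0.156), and Ms4a3, a marker of granulocyte precursors, 0.78 ± 0.19 higher (limma adjusted p = 0.171). Retnlg was 0.51 ± 0.13 higher and Stfa1 1.15 ± 0.34 higher. Among macrophage genes, Vsig4, a complement receptor of tissue macrophages, was 0.64 ± 0.19 higher, Lilrb4a 0.67 ± 0.21, the lysozyme gene Lyz2 0.43 ± 0.14 and the complement gene C1qc 0.52 ± 0.18, with limma adjusted p-values from 0.188 to 0.228. Of the mast cell, basophil and eosinophil genes, Fcer1a, which encodes the alpha chain of the IgE receptor, was 0.69 ± 0.20 higher and the mast cell protease Cpa3 0.52 ± 0.19 higher. Prg3, an eosinophil granule gene, was 2.73 ± 0.95 higher, and Ccr3, the eotaxin receptor, 1.20 ± 0.45 higher. The spread of Prg3 lay in the wild type, at 6.97 ± 2.31 (SD, n = 4) against 9.70 ± 0.14 (SD, n = 4) in the mutants. Wild type replicate 3 had the highest wild-type mean in each of the granulocyte, macrophage and mast cell lists, and wild type replicate 2 the lowest. The granulocyte mean of replicate 3 was 11.68 against 11.06 to 11.58 in the other wild-type femurs and 11.71 to 11.99 in the mutants. The mast cell mean of replicate 2 was 5.95 against 6.83 to 7.46 in the other wild-type femurs and 7.62 to 7.79 in the mutants.

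Inflammatory and interferon genes rose in femur as lists. Of the inflammatory cytokine and acute phase list, 13 of 19 genes were higher, with a median of 0.25 (camera adjusted p = 0.00146, adjusted p = 0.80 with an estimated correlation). Orm1, which encodes an acute phase protein, was 0.78 ± 0.21 higher, haptoglobin (Hp) 0.45 ± 0.15, Tnf 0.33 ± 0.10 and Nfkbia 0.26 ± 0.09. Of the interferon response list, 21 of 28 genes were higher, with a median of 0.21 (camera adjusted p = 0.00338, adjusted p = 0.80 with an estimated correlation). The immunoproteasome gene Psmb8 was 0.51 ± 0.12 higher, Ifit2 0.40 ± 0.13 and Ifit3 0.43 ± 0.17. Neither list held a gene past the limma threshold over all probes or adjusted over the list alone. At an unadjusted p under 0.05, 4 inflammatory and 3 interferon genes were higher. The genotypes overlapped in the mean log2 signal of both lists, with femurs at 7.47 to 7.86 in the wild type and 7.81 to 7.99 in the mutants for inflammatory genes and at 7.70 to 8.06 and 7.80 to 8.26 for interferon genes.

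The osteoblast and bone matrix list fell in femur, with 15 of 21 genes lower and a median of -0.15 (camera adjusted p = 0.0346, adjusted p = 0.814 with an estimated correlation). Pth1r, the receptor of parathyroid hormone, was -0.57 ± 0.16 by its brightest probe, with 1 of its 3 probes of the other sign. Dlx3, a transcription factor of osteoblasts, was -0.43 ± 0.10, alkaline phosphatase (Alpl) -0.35 ± 0.12 and the type I collagen gene Col1a1 -0.41 ± 0.14, with limma adjusted p-values from 0.168 to 0.217. Adjusted over the list alone, 1 gene of the 21 passed and 0 over all probes, against 7 lower at an unadjusted p under 0.05. The erythroid list fell, with 19 of 22 genes lower and a median of -0.17 (camera adjusted p = 0.0170, adjusted p = 0.80 with an estimated correlation), and held 0 genes past either threshold and 7 lower at an unadjusted p under 0.05. Its genes included the erythroid transcription factor Gata1 at -0.47 ± 0.14, whose probes disagreed in sign, and the red-cell skeleton gene Ank1 at -0.36 ± 0.12. The heat shock list fell, with 17 of 19 genes lower (camera adjusted p = 0.0296, adjusted p = 0.80 with an estimated correlation), Hsph1 at -0.65 ± 0.18 and Chordc1 at -0.46 ± 0.10, while Hmox1, which encodes heme oxygenase, was 0.54 ± 0.24. In it, 1 gene passed adjusted over the list alone and 0 over all probes. The adipocyte identity list rose, with 17 of 23 genes higher (camera adjusted p = 0.0345, adjusted p = 0.80 with an estimated correlation), and 0 genes past either threshold. Aqp7, the glycerol channel of adipocytes, was 0.47 ± 0.17 higher and Mest -0.53 ± 0.21.

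In the mean log2 signal per femur array, wild types and mutants overlapped for the bone matrix list (9.57 to 10.05 and 9.59 to 9.81), the erythroid list (10.84 to 11.09 and 10.63 to 10.91), heat shock (9.63 to 10.02 and 9.37 to 9.90) and adipocyte identity (7.97 to 8.29 and 8.04 to 8.49). These 4 lists, unlike the 5 immune ones, lost their camera call when single femur arrays were left out. The bone matrix list did so without wild type replicate 2 (adjusted p = 0.167), 3 (0.151) or 4 (0.0738) and without AEA001 mutant replicate 1 (0.0804), 2 (0.151) or 4 (0.0753). The erythroid list did so without wild type replicate 1 (0.0614) or 3 (0.0709) or mutant replicate 1 (0.0973). Heat shock did so without wild type replicate 1 (0.0614) or 4 (0.0738) or mutant replicate 3 (0.0751) or 4 (0.185). Adipocyte identity did so without wild type replicate 1 (0.127) or 3 (0.0560) or mutant replicate 1 (0.195) or 4 (0.151), in femur. Without both arrays that share 1 animal identifier, the adjusted p of the same lists was 0.232, 0.0919, 0.0919 and 0.167. The erythroid list also lost its call over probes above 32 on all 8 femur arrays (0.0580). Dlx3, Pth1r, Gata1, Chordc1, Hsph1, Padi4, Ms4a3, Stfa1, Vsig4, C1qc, Ccr3 and Psmb8 passed the limma threshold over all probes without wild type replicate 3, with adjusted p-values from 0.0154 for Pth1r to 0.0487 for C1qc.

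Of bone cell lists without a camera call, the osteoclast list had a median of -0.06 over 13 genes (camera adjusted p = 0.872), with cathepsin K (Ctsk) at -0.06 ± 0.14. The osteocyte list had a median of -0.02 over 6 genes (camera adjusted p = 0.734), with podoplanin (Pdpn) at -0.05 ± 0.15. The chondrocyte and growth plate list had a median of -0.08 and a mean of 0.02 over 13 genes (camera adjusted p = 0.872), with Col2a1 at -0.12 ± 0.24, and passed as lower without wild type replicate 1 (camera adjusted p = 0.0437). The Wnt list had a median of -0.0045 over 14 genes (camera adjusted p = 0.737). The B cell list, with 15 of 18 genes lower, had a camera adjusted p of 0.0560, 1 gene lower adjusted over the list alone and Cd79b at -0.21 ± 0.12 in femur. It passed as lower without wild type replicate 2 (camera adjusted p = 0.00356) or 4 (0.0331) or AEA001 mutant replicate 3 (0.00700) or 4 (0.0215).

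By single probes, 1 of 14281 passed in femur (9789 genes), a probe of Lta4h, the leukotriene hydrolase that makes a neutrophil attractant. It rose from 4.05 ± 0.11 (SD, n = 4) to 4.98 ± 0.05 (SD, n = 4), by 0.93 ± 0.09 (limma adjusted p = 0.0296), near the log2 floor of 4, which 1 of the 4 wild-type arrays exceeded. The floor thus understates the rise and the wild-type spread on which that adjusted p rested. The brighter probe of Lta4h was 0.50 ± 0.26 higher (limma adjusted p = 0.367). Next in order of p, and not past the threshold, were the DNA-binding factor Purb at -0.97 ± 0.12, the death receptor Tnfrsf25 at -1.31 ± 0.17 and Tapbp, which loads peptide on class I molecules, at 0.72 ± 0.09, each with a limma adjusted p of 0.0971. Dnmt3l was 0.90 ± 0.13, Bach1, a heme-regulated repressor, -0.83 ± 0.12, Ddx6 -0.74 ± 0.11, Padi2 -0.59 ± 0.09, the T cell factor Bcl11b -0.95 ± 0.15, Slc12a4 -0.88 ± 0.14 and Pstpip2 0.74 ± 0.12, with limma adjusted p-values from 0.117 to 0.139. At an unadjusted p under 0.05, 2412 probes (16.9%) differed, 1185 higher and 1227 lower, and the arrays of the genotypes did not overlap for 9.37% of probes, where chance gives 2.86% on average. Probes are not independent, and other splits of the animals gave 317 to 2212 femur probes at an unadjusted limma p under 0.05, with a median of 556.5. Splits that exchanged wild type replicate 3 and 1 mutant gave 1689 to 2212, and the rest 317 to 1033. The count of called probes was 702 without wild type replicate 3 and 0 without any other single femur array. It was 398 without both arrays that share 1 animal identifier. In 1 fit of all 16 arrays, where the tissues share 1 estimate of the spread, it was 38, with the Lta4h probe not tested and Tnfrsf25, Purb, Bach1, Ddx6 and Chordc1 passing, and it was 1029 without wild type replicate 3 and 0 to 8 without any other animal. The Lta4h call was also lost with a mean-variance trend and robust eBayes, where Bach1 and Ddx6 passed, and with a floor of 32, above its mean signal, where Padi2 did. Purb, Tnfrsf25, Tapbp, Dnmt3l, Bach1, Ddx6, Padi2, Bcl11b, Slc12a4 and Pstpip2 all passed without wild type replicate 3.

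**Figure D2:**
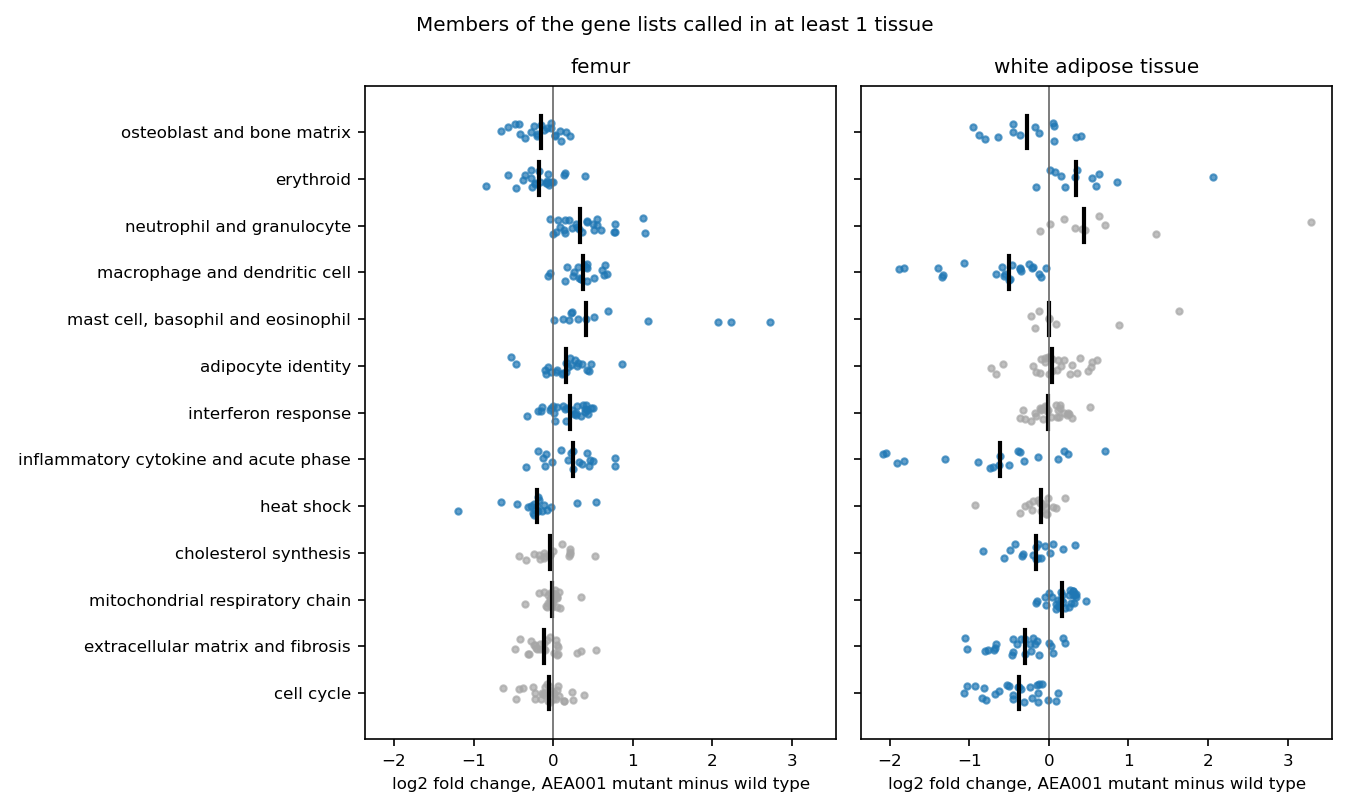
Log2 fold change of every measured member of the 13 gene lists called in at least 1 tissue, in femur (left) and white adipose tissue (right). Blue points mark lists with a camera adjusted p under 0.05 in that tissue, grey points the others, and black bars the medians, such as 0.37 in femur and -0.50 in white adipose tissue for macrophage genes.

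On a line from the wild-type mean (0) to the mutant mean (1) of the other arrays, wild type replicate 3 lay at 0.763 in femur, within the mutant range of 0.688 to 0.790. The other wild-type femurs lay between -0.185 and 0.213. In white adipose tissue, wild type replicates 1 and 2 lay at -0.657 and -0.212, wild type replicates 3 and 4 at 0.575 and 0.736, and the mutants between 0.584 and 1.18.

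**Figure D3:**
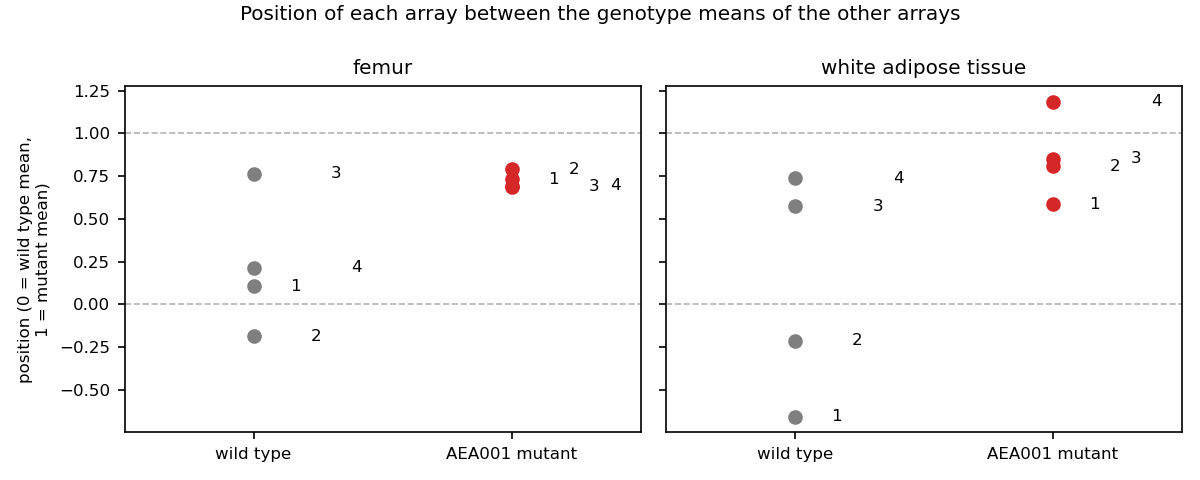
Position of each array on the line from the wild-type mean (0) to the AEA001 mutant mean (1), both computed without that array, over the tested probes of the tissue. Points are single arrays marked with their replicate number, and wild type replicate 3 lay at 0.763 in femur and 0.575 in white adipose tissue.

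The white adipose comparison asked the same of fat. By camera at its preset correlation, the macrophage, inflammatory, matrix and cell cycle lists were lower in the mutants and the mitochondrial respiratory chain list higher, while 0 of their genes passed the limma threshold over all probes and 0 lists passed with an estimated correlation. The macrophage and dendritic cell list fell, with 22 of 22 genes lower and a median of -0.50 (camera adjusted p = 2.83e-06, adjusted p = 0.654 with an estimated correlation). The inflammatory cytokine and acute phase list fell, with 15 of 19 genes lower and a median of -0.62 (camera adjusted p = 0.000306, adjusted p = 0.654 with an estimated correlation). The extracellular matrix and fibrosis list fell, with 21 of 25 genes lower and a median of -0.31 (camera adjusted p = 9.06e-06, adjusted p = 0.654 with an estimated correlation), and the cell cycle list fell, with 24 of 26 lower and a median of -0.38 (camera adjusted p = 0.000229, adjusted p = 0.654 with an estimated correlation). The respiratory chain list rose, with 24 of 28 genes higher and a median of 0.17 (camera adjusted p = 0.00493, adjusted p = 0.654 with an estimated correlation).

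Lyz2 was -1.06 ± 0.29 and C1qc -0.49 ± 0.14 in white adipose tissue, the opposite sign to femur. The mannose receptor Mrc1 of resident macrophages was -0.55 ± 0.15 and Lyz1 -0.36 ± 0.12. The monocyte chemokines Ccl8 and Ccl7 were -0.75 ± 0.12 and -2.05 ± 0.60, serum amyloid A gene Saa3 -2.09 ± 0.60 and Orm1 -0.71 ± 0.15, with limma adjusted p-values from 0.108 to 0.117. Of the matrix genes, Timp1, a metalloproteinase inhibitor, was -1.06 ± 0.28, the crosslinking enzyme Loxl2 -0.69 ± 0.17, Tgfbi -0.45 ± 0.10 and the collagen gene Col6a1 -0.68 ± 0.19. The proliferation genes Top2a and Cdk1 were -1.06 ± 0.37 and -1.03 ± 0.35, Kif23 -0.84 ± 0.23 and Prc1 -0.79 ± 0.24. In the respiratory chain list, Mdh2 was 0.46 ± 0.12 higher, Atp5g1 0.31 ± 0.08, and the complex II subunits Sdhb 0.31 ± 0.08 and Sdhc 0.30 ± 0.11. Over all probes, 0 genes of these lists passed the limma threshold. In 1 fit of all 16 arrays, where the tissues share 1 estimate of the spread, Lyz2, Mrc1, Lyz1, Saa3, Orm1, Timp1, Loxl2, Tgfbi, Col6a1, Top2a, Cdk1, Kif23, Prc1, Mdh2, Atp5g1 and Sdhb passed. That fit called 0 white adipose probes without wild type replicate 1 or 2 or AEA001 mutant replicate 4. At an unadjusted p under 0.05, 12 macrophage, 12 inflammatory, 14 matrix and 6 cell cycle genes were lower and 9 respiratory chain genes higher. Adjusted over the list alone, 3 macrophage, 9 inflammatory and 13 matrix genes passed as lower, 3 respiratory chain genes as higher, and 0 cell cycle genes.

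The wild-type white adipose arrays differed among themselves in these genes. Mean log2 signal of the macrophage list was 10.22 and 10.12 in wild type replicates 1 and 2, 9.39 and 9.18 in replicates 3 and 4, and 8.94 to 9.21 in the mutants. For the inflammatory list the values were 8.67, 8.83, 8.04 and 7.87 in the wild types and 7.58 to 7.72 in the mutants. For the cell cycle list they were 6.77, 6.55, 6.10 and 6.16 in the wild types, 5.68 to 5.91 in mutants 1, 3 and 4, and 6.51 on AEA001 mutant replicate 2, the array with femur transcripts. For the matrix and fibrosis list they were 11.10, 11.08, 10.78 and 10.78 against 10.43 to 10.69, and for the respiratory chain list 11.46, 11.44, 11.61 and 11.56 against 11.63 to 11.77.

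Of the other lists called in white adipose tissue, cholesterol synthesis fell, with 13 of 17 genes lower and a median of -0.16 (camera adjusted p = 0.0264, adjusted p = 0.654 with an estimated correlation), Dhcr7 at -0.82 ± 0.20 and squalene epoxidase (Sqle) at -0.43 ± 0.14. Its mean log2 signal overlapped between the genotypes, at 8.35 to 8.66 in the wild type and 8.16 to 8.43 in the mutants. The osteoblast and bone matrix list fell, with 9 of 14 genes lower and a median of -0.27 (camera adjusted p = 0.0264, adjusted p = 0.654 with an estimated correlation). As fixed, it shares Col1a1, Sparc, Postn and other collagen genes with the extracellular matrix and fibrosis list, so their calls are not independent. Bmp3 was -0.64 ± 0.10, the connective tissue proteoglycan lumican (Lum) -0.96 ± 0.26, Serpinf1 -0.46 ± 0.12 and Col1a1 -0.80 ± 0.25. The erythroid list rose, with 11 of 12 genes higher and a median of 0.34 (camera adjusted p = 0.0264, adjusted p = 0.654 with an estimated correlation), the globin genes Hbb-bt at 0.85 ± 0.18 and Hbb-b2 at 0.36 ± 0.13 and the heme synthesis gene Alas2 at 0.63 ± 0.18. Its mean was highest on AEA001 mutant replicate 2, the array with femur transcripts, at 8.64 against 8.02 to 8.06 in the other mutants and 7.60 to 7.82 in the wild type. Over all probes 0 genes of these 3 lists passed, while Dhcr7, Sqle, Bmp3, Lum, Serpinf1, Col1a1, Hbb-bt and Alas2 did in 1 fit of all 16 arrays. As said, that fit called 0 white adipose probes without wild type replicate 1 or 2 or AEA001 mutant replicate 4. Adjusted over the list alone, 1 cholesterol synthesis and 4 bone matrix genes passed as lower and 3 erythroid genes as higher, against 5, 6 and 4 at an unadjusted p under 0.05. The erythroid call was lost without wild type replicate 3 (adjusted p = 0.10) or AEA001 mutant replicate 2 (0.0861), the bone matrix call without wild type replicate 3 (0.0542) or mutant replicate 4 (0.0674), and the cholesterol call without wild type replicate 2 (0.102) or mutant replicates 3 (0.105) or 4 (0.0741), each in white adipose tissue. Without both arrays that share 1 animal identifier, the adjusted p was 0.0778 for erythroid, 0.0946 for bone matrix and 0.0633 for cholesterol genes. Over probes above 32 on all 8 white adipose arrays it was 0.128 for erythroid and 0.0761 for bone matrix genes, and with no filter on dim probes 0.103 for bone matrix genes.

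Adipocyte genes as a list showed no call in white adipose tissue, with 16 of 26 higher and a median of 0.04 (camera adjusted p = 0.678), 2 genes higher and 2 lower adjusted over the list alone, and Lpl at 0.01 ± 0.07. Within it, leptin (Lep) was -0.66 ± 0.19 (limma adjusted p = 0.112) and Adipoq 0.27 ± 0.09 (limma adjusted p = 0.130), and for each the genotypes did not overlap. The circadian clock list, with 11 of 16 genes higher and a median of 0.31 (camera adjusted p = 0.127), had 6 genes higher adjusted over the list alone. Triglyceride synthesis genes had a median of 0.23 over 23 genes (camera adjusted p = 0.109), with 6 higher adjusted over the list alone and Scd1 at 0.13 ± 0.08, and passed as higher without AEA001 mutant replicate 3 (camera adjusted p = 0.0182). In the skeletal muscle list, 12 of 13 genes were higher in the mutants (camera adjusted p = 0.109), with a mean of 9.29 on AEA001 mutant replicate 2 against 5.99 to 7.05 on the other white adipose arrays. It passed as higher without AEA001 mutant replicate 1 (camera adjusted p = 0.0132) or 4 (0.0399).

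By single probes, 2 of 14342 passed in white adipose tissue (9878 genes), both lower in the mutants. A probe of Cert1, the ceramide transfer protein, was at 5.03 ± 0.18 (SD, n = 4) in the wild type and an unnamed probe at 5.12 ± 0.19 (SD, n = 4), with all 4 mutant arrays of each at the floor of 4, so that they were at least 2.04-fold and 2.17-fold lower in the mutants. For both the limma adjusted p = 0.0347 rested on a mutant spread that the floor set to 0. The brightest probe of Cert1 was -0.37 ± 0.14 (limma adjusted p = 0.164). Not past the threshold, at a limma adjusted p of 0.108, were Depp1, a FoxO target, at 0.95 ± 0.12, Tmem150a at 0.70 ± 0.09, Eif3k at 0.63 ± 0.09, Abi3 at 0.63 ± 0.09, Tspyl2 at 0.67 ± 0.10 and Foxj2 at 0.51 ± 0.08. Lower at the same adjusted p were the diacylglycerol kinase gene Dgke at -0.79 ± 0.11, the RNA-binding protein gene Mex3c at -1.47 ± 0.22, the condensin gene Ncapg2 at -0.84 ± 0.13 and Bod1l at -0.99 ± 0.16. Dgke lay at 4.216 on AEA001 mutant replicate 3 and at 4 to 4.02 on the other mutant arrays, so the floor understates its fall and its mutant spread. At an unadjusted p under 0.05, 3742 probes (26.1%) differed, 1822 higher and 1920 lower, and the genotypes did not overlap for 15.7% of probes, where chance gives 2.86% on average. Other splits of the animals gave 218 to 2542 white adipose probes at an unadjusted limma p under 0.05, with a median of 388.5. The 2542 came from the split that exchanged wild type replicate 4 and AEA001 mutant replicate 1. The count of called probes was 1 without wild type replicate 2 and 0 without wild type replicate 3 or 4 or any single mutant, and both calls were lost with a mean-variance trend and robust eBayes and with a floor of 32. At a limma adjusted p under 0.10, 2 probes passed with all arrays and 2166 and 1976 without wild type replicates 3 and 4. At that threshold 4 and 1 passed without wild type replicates 1 and 2, and 0 without any single mutant. In 1 fit of all 16 arrays the count of called probes was 983, 434 higher and 549 lower, both calls and Depp1, Tmem150a, Eif3k, Abi3, Tspyl2, Foxj2, Mex3c, Ncapg2 and Bod1l among them. That count was 0 without wild type replicate 1 or 2 or AEA001 mutant replicate 4, 8, 76 and 494 without mutant replicates 3, 2 and 1, and 2063 and 1718 without wild type replicates 3 and 4.

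The genotype effect was then compared between the tissues of the same animals, over 12882 probes measured in both. The macrophage and dendritic cell list differed most by camera, with 20 of 20 genes higher in the femur effect and a median difference of 0.91 (camera adjusted p = 3.54e-09, adjusted p = 0.920 with an estimated correlation). The inflammatory cytokine and acute phase list differed by a median of 0.77 (camera adjusted p = 0.000906), the cell cycle list by 0.38 (0.00115), the interferon response list by 0.30 (0.0150) and the extracellular matrix and fibrosis list by 0.24 (0.0150). For these 4 lists too the adjusted p = 0.920 with an estimated correlation. In the erythroid list 10 of 12 genes were lower in the femur effect, with a median difference of -0.35 (camera adjusted p = 0.0499, adjusted p = 0.920 with an estimated correlation). The lowest fry adjusted p among the 6 lists was 0.209. Adjusted over the list alone, 13 macrophage, 4 inflammatory and 2 matrix genes passed as higher in the femur effect and 3 erythroid genes as lower, against 0 over all probes in this test. The erythroid call was lost without wild type replicate 1 (camera adjusted p = 0.0912) or 3 (0.204), without AEA001 mutant replicate 2 (0.0909) or without both animals of 1 identifier (0.272). The matrix call was lost without wild type replicate 1 (0.0942) or without that pair (0.0714), and the interferon call without wild type replicate 1 (0.0599) or AEA001 mutant replicate 3 (0.0691). Without wild type replicate 1 the median difference was 0.15 for the matrix list and 0.18 for the interferon list. The macrophage, inflammatory and cell cycle lists passed camera without any 1 animal and without that pair. Their median differences moved with the animal left out. The cell cycle median was 0.235 without AEA001 mutant replicate 4 and 0.575 without mutant replicate 2, the array with femur transcripts. The macrophage median ran from 0.66 to 1.11 and the inflammatory one from 0.52 to 0.97. Called only when 1 animal was left out were the respiratory chain list, lower without AEA001 mutant replicate 1 (0.0346) or 2 (0.0364), skeletal muscle, lower without mutant replicate 1 (0.0117), and, higher without mutant replicate 3, mast cell (0.0401) and adipocyte genes (0.0254). The skeletal muscle median difference was -1.10 with all animals and -0.34 without mutant replicate 2, the animal with femur transcripts on its white adipose array (camera adjusted p = 0.547).

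By single probes, 929 passed, 525 with a higher effect in femur and 404 with a lower one, and 98.6% of them had effects of opposite sign, as a selection for large differences favours, against 60.8% of all probes tested. The muscle actin gene Acta2 differed by 1.41 ± 0.21, from 0.40 in femur and -1.003 in white adipose tissue, for 1 of its probes. Upb1, of pyrimidine breakdown, differed by 1.26 ± 0.19, the cation channel gene Tmem38b by 0.96 ± 0.16, Mex3c by 2.19 ± 0.36 and the kinase gene Map2k6 by 1.07 ± 0.18. Bach1 differed by -1.47 ± 0.20, from -0.83 in femur and 0.64 in white adipose tissue. Tnfrsf25 differed by -1.55 ± 0.23, Spen by -1.04 ± 0.16, Sdcbp2 by -1.19 ± 0.19 and Purb by -1.57 ± 0.25, all with limma adjusted p-values from 0.0225 to 0.0243. The count was 0 with the animal as a fixed effect, where 3413 probes differed at an unadjusted p under 0.05, against 3740 with it as a random block. It was 0 without wild type replicate 1 or 2 or AEA001 mutant replicate 2 or 3, 1 without mutant replicate 1, 8 without mutant replicate 4, and 2670 without wild type replicate 3.

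Across 8976 genes measured in both tissues, the fold changes of femur and white adipose tissue had a Pearson r of -0.214 and a Spearman rho of -0.221. Genes are not independent replicates, and the value is a description. It lay between -0.167 and -0.259 when 1 animal was left out.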

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

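The tests of wild type replicate 3, of the shared identifier, of femur RNA, of blood or marrow cells and of gene span, the split counts of the probes called within each tissue and those of single lists were chosen after the result was seen, and those of the shared axis and of the other split counts before. Of 220 groups of 4 arrays checked for a sample far from the others, 9 met the criterion, and chance gives about 1 in 20.

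The first pattern was the count of called femur probes, 1 with all arrays and 702 without wild type replicate 3. The 2 arrays that share 1 animal identifier ranked no better than 9 of 28 pairs by correlation in femur (r 0.9882, highest 0.9910) and 16 in white adipose tissue. In femur, though, wild type replicate 3 was the array closest to AEA001 mutant replicate 4, whose r with the other mutants was 0.9855 to 0.9863. In white adipose tissue the other mutants were closer to it (0.9858 to 0.9885 against 0.9841). How alike 2 arrays of 1 animal would be is not known, so the ranks cannot tell whether both came from 1 animal. A femur array labelled wild type replicate 3 that holds RNA of a mutant femur remains a candidate explanation, since its place was 0.763, within the mutant range of 0.688 to 0.790. Whether the whole animal was a mutant cannot be told apart, since its lower place, 0.575 in white adipose tissue, lay beside 0.736 for wild type replicate 4, and those of the other wild types had an SD of 0.712. Natural spread among wild-type mice stays open, untested.

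The second pattern was femur transcripts on the white adipose array of AEA001 mutant replicate 2, where Bglap stood at 7.921 against 4 on the other mutant arrays and S100a8 at 13.26 against 8.73 to 9.26. Blood or marrow cells alone were argued against by bone and muscle probes, whose median signal was 84.7, above the floor of 16. RNA of femur in that sample may account for it, since bone, muscle and marrow probes stood at 1.77%, 1.56% and 1.31% of femur signal, a ratio of 1.35 between highest and lowest, over probes chosen for lying at or below 16 on the other 7 white adipose arrays. Bright marrow genes gave unequal shares, 37.4% for S100a8, 16.8% for S100a9, 6.32% for Camp and 3.69% for Ngp over femur means of 26306, 20273, 19621 and 22352, against an array maximum of 33738, and what set these shares stays open. S100a8, Lcn2 (19.9%) and Alas2 (10.6%) also had signals of up to 1485, 4265 and 1773 on the other white adipose arrays.

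The third pattern was the opposite effects of genotype in the tissues. The difference between tissues passed for 929 probes, and the correlation across genes was -0.214. It was -0.218 without AEA001 mutant replicate 2, and the rank correlation of effect with gene span was -0.0499 in femur and -0.102 in white adipose tissue, which argues against femur RNA in that sample and against span as causes. An axis of sample variation that both tissues share could not be told apart, since the first components within groups correlated at 0.162 between the tissues, between the 0.1 and 0.3 set beforehand, and at 0.453 and 0.723 in size with the genotype effect of femur and white adipose tissue, where they held 25.2% and 48.1% of the variance. A biological difference between tissues stays open.

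By the count of splits, 1 of 35, the real one, gave as many probes for the difference between tissues (929, highest other 219, in the split that exchanged wild type replicate 3 and AEA001 mutant replicate 1). This argues against chance but cannot exclude it, since 1 of 35 is the smallest share that the splits can give. Several patterns were also counted on the same splits. The 929 rested on single animals too, with 0 called without wild type replicate 1 or 2 or AEA001 mutant replicate 2 or 3, 1 without mutant replicate 1, 8 without mutant replicate 4, 2670 without wild type replicate 3 and 0 with the animal as a fixed effect. For the probes called within a tissue chance was left open: 1 split gave as many in femur (1, highest other 0) and in white adipose tissue (2, highest other 1), but in each tissue the real split led the next by 1 probe, and 0 were called without any single femur array other than wild type replicate 3 and 0 without 6 of the 8 white adipose arrays. At a limma adjusted p under 0.10, white adipose tissue had 2166 and 1976 probes without wild type replicates 3 and 4, against 2 with all arrays. It had 4 and 1 without wild type replicates 1 and 2, and 0 without any single mutant. Wild type replicates 3 and 4 lay nearest the mutants, at 0.575 and 0.736 on the line between genotypes. Leaving either out widens the contrast, so these counts do not bear on chance. Chance could not be excluded for the number of lists called in femur, where 17 splits gave as many (9, highest other 17), in white adipose tissue, where 13 did (8, highest other 12), or for the correlation, where 5 did (-0.214, lowest other -0.275). The other 4 of those 5 splits, from -0.216 to -0.275, were the ones that exchanged wild type replicate 3 and 1 mutant. For single lists in femur, as small a camera p came in 1 split for neutrophil, macrophage and mast cell genes, 4 for inflammatory, 9 for erythroid, heat shock and adipocyte, 10 for interferon and 13 for bone matrix. As large a median came in 8 splits for mast cell genes (0.41, highest other 0.57), 2 for neutrophil, 1 for macrophage and inflammatory, 3 for heat shock, 5 for erythroid and interferon, 7 for adipocyte and 10 for bone matrix. In white adipose tissue as small a p came in 1 for matrix and fibrosis, inflammatory and bone matrix genes, 2 for respiratory chain, 3 for macrophage, 7 for erythroid, 11 for cell cycle and 12 for cholesterol synthesis. As large a median came there in 1 for inflammatory, respiratory chain and erythroid genes, 2 for macrophage, 3 for matrix and fibrosis and bone matrix, 5 for cell cycle and 6 for cholesterol synthesis.

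The effect differed between tissues by test for Acta2 (1.408), Upb1 (1.262), Tmem38b (0.9604), Mex3c (2.188), Map2k6 (1.072), Bach1 (-1.474), Tnfrsf25 (-1.55), Spen (-1.037), Sdcbp2 (-1.193) and Purb (-1.571). It differed by camera for the macrophage (0.9092), inflammatory (0.7679), cell cycle (0.3841), interferon (0.2975), extracellular matrix (0.2386) and erythroid (-0.3474) lists, as medians of femur minus white adipose tissue. With an estimated correlation the adjusted p = 0.920 for each of these 6 lists, and fry called 0 of them.

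Single arrays stood apart from the other 3 of their group for further genes. In femur, S100a8 was 14.81 on AEA001 mutant replicate 1 against 14.69 to 14.71, and Gata1 7.755 on the same array against 8.07 to 8.13. Lta4h by its brighter probe was 6.874 on mutant replicate 4 against 7.90 to 8.03, Stfa1 10.52 on mutant replicate 3 against 11.13 to 11.16 and Dgat2 9.634 on wild type replicate 2 against 9.86 to 9.89. In white adipose tissue, Dgke was 4.216 on mutant replicate 3 against 4 to 4.02 and Ece2 7.005 on wild type replicate 4 against 7.50 to 7.56.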

How the results depend on the processing

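The floor, offset scale, stricter dim-probe filter, renormalization, adjusted p of 0.20, gene lists of the tissue difference and omissions from the fit of all 16 arrays were tests chosen after the data were seen. The count of called probes was 1 in femur and 2 in white adipose tissue. It became 2 and 0 with no filter, 3 and 7 with a mean-variance trend and robust eBayes (0 of the main calls among them), 0 and 1 with 1 probe per gene, 398 and 0 without the 2 arrays that carry 1 animal identifier, 4 and 11 with a floor of 32 (again 0 of them), 0 and 0 with log2 of value plus 16, 0 and 0 with probes above 32 on all 8 arrays, 38 and 983 in 1 fit of all 16 arrays (the femur call not tested, both white adipose calls kept), and 810 and 3937 at an adjusted p under 0.20. In femur it was 2 with array weights and 5 at an adjusted p under 0.10. Leaving out 1 replicate gave 0 to 702 in femur and 0 to 3 in white adipose tissue. At an unadjusted p under 0.05 the limma counts were 2412 and 3742. The 929 probes of the difference of the genotype effect between femur and white adipose tissue became 178 with no filter, 1419 with the trend, 2032 without the 2 animals of 1 identifier, 2345 and 4182 at an adjusted p under 0.10 and 0.20, and 0 to 2670 without 1 animal, where the 2670, without wild type replicate 3, held 924 of the 929. Gene lists called were 9 in femur and 8 in white adipose tissue, 0 and 0 by camera with estimated correlation, 0 and 0 by fry, and 5 in white adipose tissue without the 2 arrays of 1 identifier. For the tissue difference 6 lists were called, 3 to 8 without 1 animal, 0 with estimated correlation and 0 by fry. Against 0 endothelin genes, 1 was called without the 2 arrays of 1 identifier, Ece1 in femur, and 1 in the fit of all 16 arrays, Mme in white adipose tissue. The fold change of Ednrb, white adipose tissue (endothelin pathway) was 0.02 and went from -0.0165 to 0.0529 without 1 replicate, with the opposite sign also at -0.00567 and, after cyclic loess, at -0.00872. The correlation across genes kept its sign in all alternatives run, from -0.167 to -0.263. Fewer arrays were fitted in each omission; for the other shifts the cause was not tested.

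With the replicate number as a block (replicate block), femur gave 0 called probes and white adipose tissue 0, with 2115 and 3999 at an unadjusted limma p under 0.05, and 10 and 9 lists. Same-numbered arrays of the genotypes correlated at -0.05, 0.03, 0.06 and -0.07 in femur and 0.33, 0.10, -0.06 and 0.33 in white adipose tissue. At a limma adjusted p under 0.10, the block moved the count from 5 to 0 in femur and from 2 to 1514 in white adipose tissue. The femur values gave no sign of pairing by number, while in white adipose tissue shared variation by number is left open. With the animal as a fixed effect (replicate block) the difference between tissues gave 0, with 3413 at an unadjusted limma p under 0.05.

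Among named genes, 1897 results kept their side of the threshold, 3 took the opposite sign and 85 passed only under the alternative: in femur 22 without wild type replicate 3 and 15 without the pair of 1 identifier, in the fit of all 16 arrays 5 in femur and 35 in white adipose tissue, and over both tissues 4 with the trend and 4 with a floor of 32. Each named gene was followed by its brightest probe, which did not pass with the main settings for any of them. A kept side therefore means a result that stayed short of the threshold, not a call that held. The probes called within a tissue were not among these results. For lists 186 kept their call and 69 lost it, for lists of the tissue difference 46 and 20, and for genes named for that difference 102 and 68. Not run were background correction from the unnormalized signals (neqc, other offset, none), a median shift, cyclic loess in place of quantile, the detection filter and the chip as a block, since those columns matched no sample, and the correlation over called genes, which were too few. Signal over background limits dim probes, as the called ones lay near the floor.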

Other observations

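In femur, Nkg7, a granule gene of cytotoxic cells, was 0.56 ± 0.17 higher and the T cell receptor gene Cd3d 0.44 ± 0.14 higher (moderated SE, 4 arrays per genotype, limma adjusted p = 0.187 and 0.197), while the T and NK cell list had a median of 0.20 (camera adjusted p = 0.328). Adjusted over the list alone, 3 of its genes were higher and 1 lower, against 0 over all probes.

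In white adipose tissue, 11 of 12 genes of the brown and beige adipocyte list were higher, with a median of 0.29 (camera adjusted p = 0.0844). Cidea, a lipid droplet gene, was 0.49 ± 0.12 higher (limma adjusted p = 0.112), and Cox8b 0.21 ± 0.14. The list passed as higher without wild type replicate 4 (camera adjusted p = 0.0482) or AEA001 mutant replicate 1 (0.0225).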
